A study of Homo sapiens with 6 samples.

How the data were processed

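The series measured messenger RNA in MDA-MB-231, a human triple-negative breast cancer cell line, on 1-colour Affymetrix arrays of 54675 probe sets. A probe set is a group of short oligonucleotides that together read 1 stretch of transcript. The labels name 6 arrays: 3 from cells that stably carried a short hairpin RNA (shRNA) against MYOSIN10, the gene now named MYO10, and 3 from cells that carried a scrambled shRNA. Per the labels' protocols, cells grew in L-15 medium with serum, total RNA was extracted with a phenol reagent, checked for integrity and purified on columns with DNase, and biotin-labelled cRNA was made with a 3' in vitro transcription kit. That chemistry favours the 3' end of transcripts. The labels number the samples 1 to 3 in each group and do not say whether the numbers stand for separate cultures, so every p-value measures the spread between these samples, which may be technical.

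The submitters' processing notes name MAS5, Affymetrix's method that summarises each probe set on its own array and scales the array to a common level. Its version, scaling target and lower limit are not given in the sources used here. The deposited values are log2 signals, a scale read from the values: after 2 is raised to each value, the mean with 2% trimmed from each end was 499.91 to 499.92 on every array. An exact 0 is the lower limit of the deposited log2 scale and was held by 0.754% to 1.01% of the probe sets per array. Arrays carry no read depth, and the number of arrays, 3 per group, limits the precision. Because each array was scaled to the same mean, a change of the total RNA per cell would not be visible in these values.

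The deposited values were returned to the linear scale, 16 was added, and log2 was taken again, which holds down the noise of dim probe sets and understates the fold change of low signals. A probe set was kept where it reached its array's 40th percentile on at least 3 of the 6 arrays, which left 33370. Gene symbols came from the platform's annotation table, which listed 1 symbol for 41097 probe sets, several for 1801 and none for 11777. For 41043 of the 41097, the symbol was updated by Entrez gene number through the RefSeq table of assembly GRCh38.p14. Probe sets without a single listed symbol are unnamed here, not without a gene, and were tested apart. Each gene was represented by its kept probe set with the highest mean over all 6 arrays, which gave 14174 genes. No coordinates are printed, since no genome build is named with the probe sets, and the RefSeq table served for names and for which genes are adjacent.

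Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of variance on signal, group as the sole term, two-sided), and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are MYOSIN10 shRNA over scramble shRNA. All adjusted p-values of genes are from this test over all genes tested unless another scope is named. For 28 gene lists drawn from general knowledge, limma's camera with a preset inter-gene correlation of 0.01 asked whether a list's genes shifted against all other genes, adjusted by Benjamini-Hochberg over the lists. Every list had at least 8 measured genes. Counts of called members were also made with the adjustment over the list alone. The list of groups, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule took MYO10, then the 12 largest rises and 12 largest falls among called genes whose groups did not overlap and whose brighter group mean reached the median of the genes tested. From each list it took up to 4 called members with the largest change, or, in a list with no call, up to 2 members with the smallest p. Genes named outside this rule are marked as chosen after their values were seen. Some results are not reported here.

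The steps were tested on simulated data for this comparison, with 200 of 14174 genes changed in each of 10 runs. A true log2 change of 1 was called in 72.5% of cases and a change of 0.5 in 37.1%, and 6.96% of calls were false. In 10 runs with no change, 1 gene and 0 lists were called in all. The simulated noise was drawn independently for each gene, without correlation between genes or shared array effects. These runs therefore cannot show how often a list of correlated genes would be called without a change. The noise was also normal, with each gene's spread taken from the same variance model that the test uses, so that model held by design. The share of false calls in the real data may therefore differ. Alternatives were another pseudocount, filter, scaling between arrays, probe set rule or variance model, array weights, the replicate number as a block, each array left out in turn, an estimated inter-gene correlation and limma's fry test. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.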

Results

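Expression was profiled in 3 MDA-MB-231 samples with stable MYOSIN10 shRNA and 3 with stable scramble shRNA, 1 array each, and the comparison asks which transcripts differ when the message of MYO10, a motor protein that travels to the tips of filopodia, is lowered. The 6 arrays were alike, with correlations across genes from 0.978 to 0.987 over the 15 pairs. The first principal component held 29.9% of the variance and placed scramble arrays 1 and 3 at -28.0 and -25.7 and the MYOSIN10 shRNA arrays between 14.5 and 20.1. Scramble array 2 lay at 4.45 on that component, and its mean correlation was 0.982 with its own group and 0.983 with the other. The second component held 23.4% of the variance. It placed scramble array 2 at -23.7 and MYOSIN10 shRNA array 2 at -19.85, and the other arrays between -0.516 and 22.2.

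MYO10 was lower in the cells with MYOSIN10 shRNA. Its brightest probe set had a log2 signal of 11.8 ± 0.21 (SD, n = 3) with scramble shRNA and 10.91 ± 0.42 (SD, n = 3) with MYOSIN10 shRNA, so that the message stood at 54.2% of the scramble level. The log2 fold change was -0.88 ± 0.18 (SE; limma, Benjamini-Hochberg adjusted p = 0.0303), and all 3 knockdown arrays lay below all 3 scramble arrays. Of the 5 probe sets assigned to MYO10, 4 had negative log2 fold changes and 3 had no overlap between the groups. Tested among all kept probe sets, the 4 dimmer ones stood at -0.74 (limma adjusted p = 0.0514), -0.84 (0.126), -0.58 (0.163) and 0.31 (0.647). MYOSIN10 shRNA array 2 kept more of the message (11.39 against 10.7 and 10.64 on knockdown arrays 1 and 3). The call ended without scramble array 1 (limma adjusted p = 0.0643), scramble array 3 (0.142), MYOSIN10 shRNA array 1 (0.137) or MYOSIN10 shRNA array 3 (0.143), and without the variance trend (0.243), and it held in 11 of the 20 alternatives, over which the log2 fold change of MYO10 ran from -1.12 to -0.55.

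**Figure D1:**
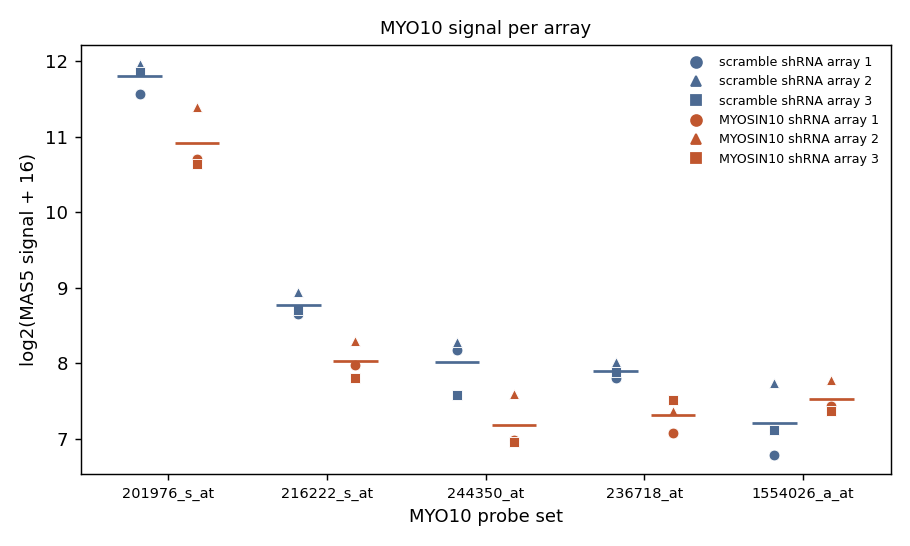
Log2(MAS5 signal + 16) of the 5 MYO10 probe sets on each of the 6 arrays, with scramble shRNA in blue, MYOSIN10 shRNA in orange, marker shapes for arrays 1 to 3 and horizontal bars for group means. The knockdown mean lies below the scramble mean for 4 probe sets and above it for 1.

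Counting MYO10 itself, 229 of 14174 genes changed, 164 higher and 65 lower in the MYOSIN10 shRNA cells (limma with Benjamini-Hochberg adjustment). Of these, 41 moved at least 2-fold, 35 upward and 6 downward, and the median absolute log2 fold change of the called genes was 0.70. For each of the 229, the 3 arrays of one group lay entirely to one side of the other 3. Over all genes tested, 19.8% showed such a separation, against 10% by chance for 3 against 3, and 2108 had an unadjusted p under 0.05. Without scramble array 2 the number of called genes was 964, and it was 78 without scramble array 1, 79 without scramble array 3, 66 and 81 without MYOSIN10 shRNA arrays 1 and 3, and 1224 without both arrays numbered 2. The number that moved at least 2-fold was 149 without scramble array 2, 27 and 24 without scramble arrays 1 and 3, 26 without MYOSIN10 shRNA array 1 and 165 without both arrays numbered 2. With eBayes run without a trend of variance on signal, 7 genes passed, all higher, 6 of them among the 229. They were SCCPDH, PMEPA1, DENND6A, UGT8, the dim RSAD2 (see the interferon list), CHMP4B and POM121L12 (the last 2 chosen after their values were seen). Of the called list members named below, FMNL2, NEDD9, PLAU, EFNB2, FZD7, OASL, NDRG1 and PSAT1 passed without any single array, while CDC42EP3, TNS3, FBN1, CCNE1, AURKB, DDB2, HERC6, NFKBIA, ATF4 and UQCRC2 did not without at least 3 of the 6, with a largest limma adjusted p between 0.0674 (TNS3) and 0.202 (NFKBIA).

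The largest rise was that of EREG, an epidermal growth factor receptor ligand, whose log2 signal went from 8.06 ± 0.75 to 9.96 ± 0.23 (SD, n = 3 each; log2 fold change 1.90 ± 0.29 SE, limma adjusted p = 0.00734). SCCPDH, an oxidoreductase of the saccharopine dehydrogenase family, rose by 1.64 ± 0.10 (SE, limma adjusted p = 1.71e-05) and PMEPA1, a target and brake of TGF-beta signalling, by 1.55 ± 0.11 (SE, limma adjusted p = 2.96e-05). The others among the 12 largest rises of genes whose brighter group mean reached the median signal of the genes tested were 2.62-fold for the interferon-induced IFIT1, 2.55-fold for UGT8 (which makes galactosylceramide), 2.51-fold for the immediate early transcription factor EGR1, 2.46-fold for CLIC3, 2.41-fold for SERINC2, 2.38-fold for the mitochondrial prohibitin PHB2, 2.34-fold for UBALD2 and 2.30-fold for LFNG, a glycosyltransferase that modifies Notch. DENND6A, an exchange factor for Rab proteins, rose with a log2 fold change of 1.35. Of these 12, 11 stayed called without any single array, and EGR1 did not without scramble array 3 (limma adjusted p = 0.0567) or MYOSIN10 shRNA array 1 (0.0664) or 3 (0.0681). The second probe set of UBALD2 stood at 0.19. Some dimmer called genes, such as RSAD2 and MUC1 (see their lists), had larger values than most of these 12.

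Among called genes above the same signal level, asparagine synthetase, ASNS, showed the largest fall, from 11.68 ± 0.41 to 10.3 ± 0.0076 (SD, n = 3 each; log2 fold change -1.38 ± 0.16 SE, limma adjusted p = 0.00216). Falls of 2.31-fold in the TNF family cytokine TNFSF15, 2.16-fold in the RNA-binding protein CELF2 and 1.89-fold in the chemokine CXCL3 came next. MYO10 itself stood among the 12 largest falls, together with PIGL, SERTAD4-AS1, POU2F2, the long noncoding RNA DANCR, ASPH, the chromatin protein HMGA2 and HABP4, whose log2 fold changes ran from -0.90 (PIGL) to -0.78 (HABP4). Another probe set did not follow for PIGL (-0.045, 0.13 and 0.24), HABP4 (-0.23 and 0.080), HMGA2 (0.074, 0.11 and -0.021 for 3 of 5 others) and ASPH (0.28 for 1 dim probe set of 6 others). Over all called genes, 147 had another kept probe set, and the next brightest had the same sign in 130. Calls of ASNS, TNFSF15, PIGL and HMGA2 held without any single array, and those of the other 8 did not, with a largest limma adjusted p between 0.0531 (CXCL3) and 0.215 (DANCR).

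**Figure D2:**
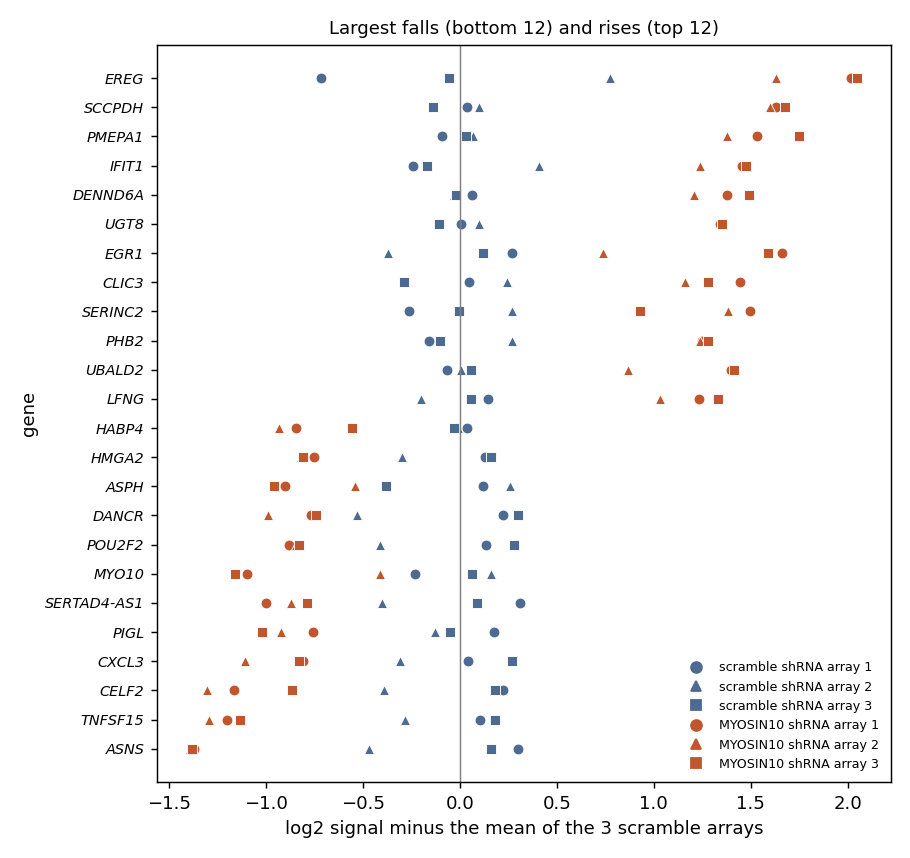
Log2 signal of each array minus the mean of the 3 scramble arrays for the 12 largest rises and 12 largest falls, with scramble shRNA in blue, MYOSIN10 shRNA in orange and marker shapes for arrays 1 to 3. The groups do not overlap for any of these genes, as the rule that chose them required, and scramble array 2 lies toward the knockdown arrays for EREG, IFIT1, ASNS and DANCR.

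Most genes of filopodia and of the actomyosin machinery did not pass. The target MYO10, which was called lower, belonged to neither the filopodium list nor the myosin list and is not counted in them. Among 27 measured filopodium genes, the formin FMNL2 rose by 0.75 on the log2 scale (limma adjusted p = 0.00345) and CDC42EP3, an effector of the GTPase CDC42, rose 1.43-fold (limma adjusted p = 0.0394), 0 fell and 25 did not pass, with 7 at an unadjusted p under 0.05. Adjusted over the list alone, 2 members rose and 1 fell, the latter being the actin nucleation promoter WASL at -0.40 (chosen after its values were seen). As a list, filopodium genes did not shift (camera adjusted p = 0.88). In the myosin family of 22 measured genes, 0 passed over all genes tested and 4 had an unadjusted p under 0.05. MYH10, a nonmuscle myosin heavy chain, stood at 0.57 (limma adjusted p = 0.0546) and the light chain MYL12A at -0.34 (limma adjusted p = 0.0812), and adjusted over the list alone 2 members were higher and 1 lower (camera adjusted p = 0.321).

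Most adhesion and matrix genes did not pass, and of the 4 that did, 3 were higher and 1 lower. In the focal adhesion list of 27, the scaffold protein NEDD9 rose 2.20-fold (limma adjusted p = 0.00611) and the tensin TNS3 rose 1.67-fold (limma adjusted p = 0.00972), and 25 did not pass, with 7 at an unadjusted p under 0.05. The other kept probe sets of NEDD9, all dimmer, gave 1.17, -0.17 and 0.58. Adjusted over the list alone, 2 focal adhesion genes rose and 2 fell. Of 19 integrin genes, 0 passed over all genes tested, 2 had an unadjusted p under 0.05 and 1 was lower when adjusted over the list alone. That gene, ITGA1, stood at -1.05 ± 0.24 (SE, limma adjusted p = 0.0582), while ITGA2 stood at 0.21 (limma adjusted p = 0.246). Fibrillin 1, FBN1, rose 1.56-fold (limma adjusted p = 0.0393) as the single call among 40 extracellular matrix genes, against 3 higher and 4 lower over the list alone and 12 at an unadjusted p under 0.05. In the list of 31 matrix protease and invadopodium genes, the urokinase PLAU fell by 0.75 on the log2 scale (limma adjusted p = 0.00162) with no overlap between the groups, and over the list alone WASL passed with it. Camera placed the lists of focal adhesion (adjusted p = 0.791), extracellular matrix (0.791), integrins (0.88) and matrix proteases (0.094) short of the threshold. The protease list, with a median of -0.048, passed in 6 of 19 alternatives, among them without scramble array 1 (-0.095, camera adjusted p = 0.037) or 2 (-0.12, 0.0247) or MYOSIN10 shRNA array 1 (-0.069, 0.0342) or 3 (-0.062, 0.0432), and its median was 0.013 without scramble array 3. The arrays numbered 2 were lower than the other 4 in both the matrix and the protease list, each with a median of -0.12 (camera adjusted p = 0.00787). Here and below, this contrast was chosen only after these arrays were seen to differ, so small p-values are no independent evidence. It was run with the preset correlation of 0.01 and not with an estimated correlation.

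The interferon response list shifted upward, with 6 of its genes called. Of 40 measured members, 34 had positive log2 fold changes, with a median of 0.29 (camera adjusted p = 9.95e-09; adjusted p = 0.266 with an estimated correlation). The median was 0.18 without scramble array 2, where the list still passed (camera adjusted p = 2.52e-05). Over all genes tested 6 rose, 0 fell and 34 did not pass, and adjusted over the list alone 12 rose and 0 fell, out of 15 with an unadjusted p under 0.05. The antiviral IFIT1 rose from 8.23 ± 0.36 to 9.62 ± 0.13 (SD, n = 3 each; limma adjusted p = 0.00274), the oligoadenylate synthetase-like OASL rose by 1.25 on the log2 scale and the ubiquitin ligase HERC6 rose 1.63-fold. IFIT2 at 1.56-fold and IFIT3 at 1.38-fold, chosen after their values were seen, also rose. The sixth call, RSAD2, the antiviral protein viperin, had a scramble level of 4.38 ± 0.17 (SD, n = 3), close to the floor that the added 16 sets, so that its value of 1.84 (limma adjusted p = 0.0447) has no firm size. Over 19 alternatives the value of RSAD2 ran from 0.72 to 3.41 and its adjusted p from 0.0169 to 0.427, and the call held in 10.

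Immediate early and heat shock genes also shifted upward, 26 of 31 with positive values and a median of 0.17 (camera adjusted p = 0.00103; adjusted p = 0.419 with an estimated correlation). EGR1 was the single call over all genes tested, while 4 members rose and 0 fell when adjusted over the list alone, out of 9 with an unadjusted p under 0.05. EGR1 stood at 10.55 ± 0.33 and 11.88 ± 0.52 (SD, n = 3 each; limma adjusted p = 0.0121), and its other 2 kept probe sets gave 1.24 and 1.03.

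Epithelial genes shifted upward as a list, 19 of 23 with positive values and a median of 0.18 (camera adjusted p = 0.00367; adjusted p = 0.434 with an estimated correlation), and the median was 0.31 without MYOSIN10 shRNA array 2. MUC1, a mucin of the apical surface, rose 2.99-fold from a low 6.47 ± 0.35 to 8.05 ± 0.40 (SD, n = 3 each; limma adjusted p = 0.00964), and was the single call over all genes tested. The other kept probe sets of MUC1, both dimmer, gave smaller log2 fold changes of 0.61 and 0.77, against 1.58. Adjusted over the list alone, 6 rose and 0 fell, out of 8 with an unadjusted p under 0.05, and these included the keratins KRT19 at 0.46, KRT8 at 0.34 and KRT18 at 0.30 (the last 2 chosen after their values were seen). The call of MUC1 ended without scramble array 1 (limma adjusted p = 0.0577) or 3 (0.057) or MYOSIN10 shRNA array 1 (0.0705) or 3 (0.0722). Mesenchymal genes, 17 measured, had 0 calls over all genes tested, 5 with an unadjusted p under 0.05, and 1 higher and 1 lower over the list alone (camera adjusted p = 0.514). The calcium-binding S100A4 stood at 0.75 (limma adjusted p = 0.0764) and the ecto-nucleotidase NT5E at -0.26 (limma adjusted p = 0.0875).

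The unfolded protein and amino acid stress list shifted downward, 27 of 38 with negative values and a median of -0.093 (camera adjusted p = 0.00367; adjusted p = 0.691 with an estimated correlation). The 3 that fell, over all genes tested and over the list alone alike, were ASNS, the serine synthesis enzyme PSAT1 at -0.77 ± 0.11 (SE, limma adjusted p = 0.00651) and the transcription factor ATF4 at -0.50 ± 0.085 (SE, limma adjusted p = 0.0137), and 0 rose. All 3 belong to the amino acid side of the list, as the known activator of that response and its targets. The arrays numbered 2 were lower than the other 4 in this list (median -0.14, camera adjusted p = 0.00559). The list's call ended without scramble array 3 (median -0.049, camera adjusted p = 0.0533), and its median was -0.16 without scramble array 2 (camera adjusted p = 0.000305).

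Hypoxia and glycolysis genes shifted upward, 26 of 33 with positive values and a median of 0.10 (camera adjusted p = 0.0023; adjusted p = 0.634 with an estimated correlation). NDRG1, a stress-responsive gene induced by low oxygen, rose 1.47-fold (limma adjusted p = 0.00578), and it was the single call both over all genes tested and over the list alone. Cholesterol synthesis genes shifted upward with a median of 0.12 (camera adjusted p = 0.0434; adjusted p = 0.634 with an estimated correlation), although 0 of 22 passed over all genes tested and 6 had an unadjusted p under 0.05. Over the list alone 2 rose, the fatty acid desaturase SCD at 0.50 and the transcription factor SREBF1 at 0.79 (limma adjusted p = 0.107 and 0.11 over all genes tested). Neither is an enzyme of cholesterol synthesis, and no other member of the list passed in either scope. The call of the cholesterol list held in 6 of 19 alternatives and ended, among others, with the stricter filter (camera adjusted p = 0.0928), with quantile normalization (by a margin that rounding hides), with the mean of a gene's probe sets (0.0572) and without both arrays numbered 2 (camera adjusted p = 0.0726). It also ended without scramble array 2 (median 0.11, camera adjusted p = 0.204) or 3 (0.13, 0.0548) or MYOSIN10 shRNA array 1 (0.083, 0.0781) or 3 (0.081, 0.166).

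Ribosomal protein genes shifted upward by a small amount, 34 of 38 with positive values and a median of 0.087 (camera adjusted p = 0.00134; adjusted p = 0.805 with an estimated correlation). Here 0 genes passed over all genes tested or over the list alone and 3 had an unadjusted p under 0.05, with RPS7 at 0.16 and RPL18 at 0.18. The call ended under quantile normalization (median 0.017, camera adjusted p = 0.739) and without scramble array 2 (median 0.062, camera adjusted p = 0.12), and the median was 0.057 without scramble array 1 and 0.13 without scramble array 3. Without _s_at and _x_at probe sets camera's direction turned, placing the ribosomal list below the other genes (median 0.053, camera adjusted p = 0.99). The arrays numbered 2 were lower than the other 4 in this list (median -0.064, camera adjusted p = 0.00491).

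Signalling lists held few calls, and none passed as a list. PMEPA1 was the one TGF-beta and BMP gene of 29 to pass over all genes tested, against 6 higher and 1 lower over the list alone (camera adjusted p = 0.459). In NF-kB and cytokine genes, the chemokine CXCL3 fell and the inhibitor NFKBIA rose 1.31-fold (limma adjusted p = 0.0403), with 29 of 31 not passing and 1 in each direction over the list alone (camera adjusted p = 0.688). The other kept probe set of NFKBIA, a dimmer one, stood at 0.050. The ephrin EFNB2 rose 2.01-fold (limma adjusted p = 0.00148) as the single call among 25 axon guidance genes, over the list alone too (camera adjusted p = 0.723). The Wnt receptor FZD7 rose by 0.59 on the log2 scale (limma adjusted p = 0.00526) among 25 Wnt genes, with 3 higher over the list alone (camera adjusted p = 0.15). The Wnt list passed in 1 of 19 alternatives (camera adjusted p = 0.0245 with the mean of a gene's probe sets). EREG was the one call among 30 growth factor receptors and ligands, where 2 were higher and 1 lower over the list alone (camera adjusted p = 0.88). Of 25 YAP-TEAD targets, 0 passed in either scope and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.094), with NT5E at -0.26 and IGFBP3 at -0.75 (limma adjusted p = 0.0875 and 0.15). This list passed in 2 of 19 alternatives, with the mean of a gene's probe sets (camera adjusted p = 0.0113) and without scramble array 1 (0.037). The arrays numbered 2 were lower than the other 4 in the NF-kB list (median -0.25, camera adjusted p = 2.7e-05) and the TGF-beta list (median -0.14, camera adjusted p = 0.0148).

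Among cell cycle genes, the cyclin CCNE1 rose 1.71-fold (limma adjusted p = 0.0174) and the mitotic kinase AURKB rose 1.57-fold (limma adjusted p = 0.0341), each the single call of its list in both scopes. Neither the 42 G1/S genes (camera adjusted p = 0.688) nor the 54 G2/M genes (camera adjusted p = 0.192) shifted as a list, although the G2/M list passed without scramble array 2 (0.0236) or MYOSIN10 shRNA array 1 (0.00783). The arrays numbered 2 were higher than the other 4 in both (medians 0.047 and 0.10, camera adjusted p = 0.00911 and 0.000113). The p53 target DDB2 rose 1.64-fold (limma adjusted p = 0.0156), again the single call of 22 (camera adjusted p = 0.723). UQCRC2, a subunit of respiratory complex III, rose 1.25-fold (limma adjusted p = 0.0424) as the single call among 40 oxidative phosphorylation genes (camera adjusted p = 0.197, and 0.0321 without scramble array 3). Its other kept probe sets gave 0.25 and, for a dim one, -0.048.

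Markers of other cells and reference genes gave 0 calls over all genes tested. Breast luminal markers (14 measured) had 1 member higher, KRT19, and 1 lower, XBP1 at -0.35, over the list alone, and 5 with an unadjusted p under 0.05 (camera adjusted p = 0.723). Fibroblast and endothelial markers (9 measured) included ACTA2 at 0.89 ± 0.48 (SE, limma adjusted p = 0.425) and LUM at 0.65 (limma adjusted p = 0.484). Without scramble array 2 ACTA2 stood at 0.24, without scramble array 3 ACTA2 stood at 1.32 and LUM at 0.35, and neither passed in any alternative. This list had a camera adjusted p of 0.608, with 0 members at an unadjusted p under 0.05. Blood cell markers (10 measured) included LAPTM5 at 0.33 and LCP1 at -0.38 (limma adjusted p = 0.205 and 0.296; camera adjusted p = 0.999). Of 25 housekeeping genes, SDHA stood at 0.29 and CHMP2A at 0.23 (limma adjusted p = 0.142 and 0.193; camera adjusted p = 0.459). The housekeeping median was 0.041, and it was -0.019 under quantile normalization, 0.010 without scramble array 1 and 0.069 without scramble array 3.

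**Figure D3:**
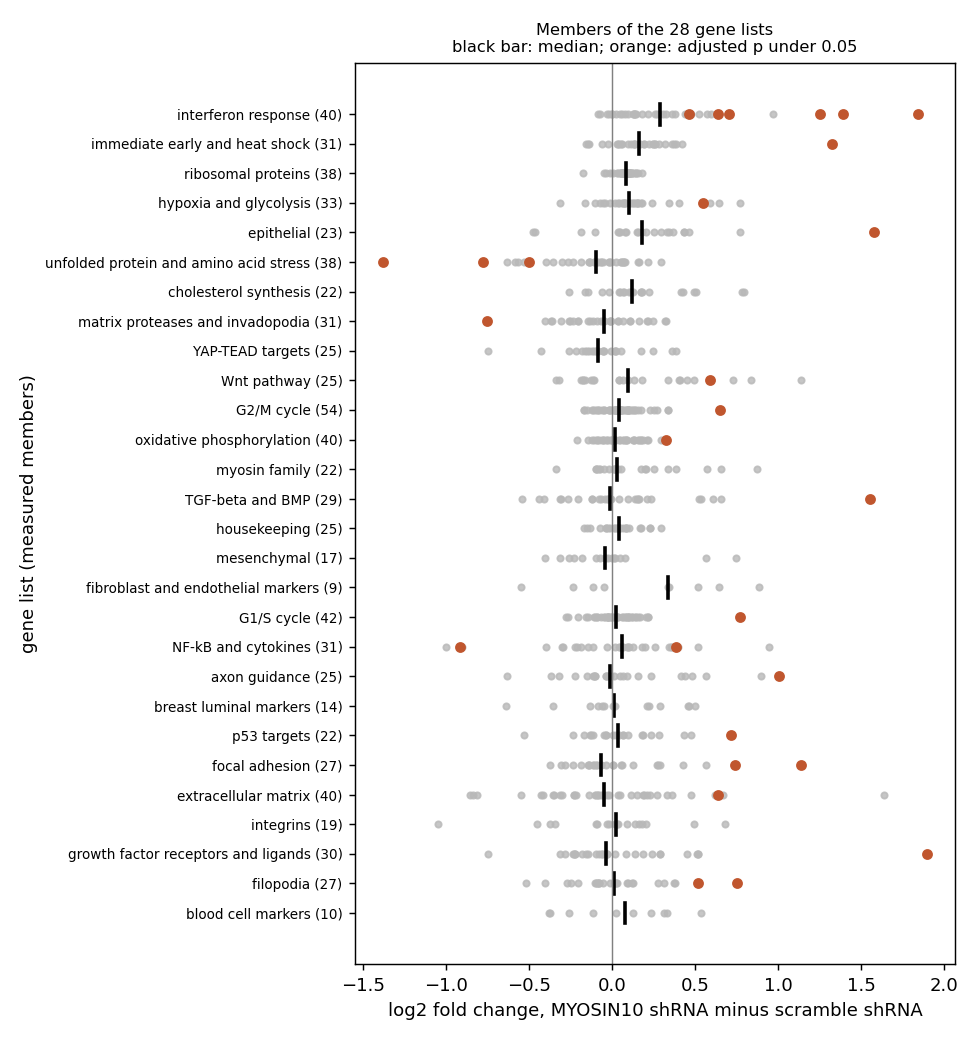
Log2 fold change, MYOSIN10 shRNA minus scramble shRNA, of every measured member of the 28 gene lists, ordered by the camera p from the smallest at the top, with a black bar at each list's median and orange points for genes with an adjusted p under 0.05. Interferon response genes lie mostly to the right of 0 with a median of 0.29, and ASNS is the leftmost orange point at -1.38.

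In all, 7 of the 28 lists passed with camera's preset correlation and 0 passed with an estimated correlation, under which 3 had an unadjusted p under 0.05. Of 19 alternatives, the call held in 17 for the interferon list and 16 each for the immediate early and hypoxia lists. It held in 15 each for the epithelial and unfolded protein lists, 13 for the ribosomal list and 6 for the cholesterol list. All 7 calls ended with the estimated correlation and with fry. The other alternatives kept the preset correlation, so the calls that held in them do not test that setting. The estimated correlations of the 7 lists, all above the preset value, ran from 0.029 (immediate early) to 0.69 (ribosomal). Median, mean and test differed in sign for the lists of filopodia, integrins, focal adhesion, extracellular matrix, growth factors, axon guidance, TGF-beta, NF-kB and blood cell markers, none of which passed.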

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

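The test of probe sets without a single gene symbol was chosen only after the gene results had been seen. Outside the 14174 genes, 6115 kept probe sets had several symbols or none listed, and they had no part in the gene comparison. Of these, 25 passed limma's test with Benjamini-Hochberg adjustment over the 6115, 21 higher and 4 lower with MYOSIN10 shRNA, and 569 had an unadjusted p under 0.05. Their log2 fold changes ran from -1.54 to 1.80. They are unnamed here, and no explanation was tested for them.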

How the results depend on the processing

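Leaving out both arrays numbered 2 and running camera without the variance trend were settings chosen only after the data had been seen. No direction of the 44 called genes named by the rule turned under any setting, but many calls ended: 39 without the variance trend, 16 with the mean of a gene's probe sets, 13 with no filter, 7 of 35 without _s_at and _x_at probe sets, and 20, 0 and 18 without scramble arrays 1, 2 and 3 and 19, 8 and 17 without MYOSIN10 shRNA arrays 1, 2 and 3. Calls were also gained: of the 19 named genes not called, 12 passed with array weights, 10 without scramble array 2 and 13 without both arrays numbered 2, among them MYH10, ITGA1, S100A4 and IGFBP3 in all 3 settings. Other pseudocounts, the stricter filter, quantile normalization and median scaling kept the numbers of called genes within 1.5 times of 229. The share of higher genes was 76.6% with median scaling and 72.2% with quantile normalization, against 71.6%. It moved further in other settings: 62.6% with array weights, 57.8% without scramble array 2, 56.7% without both arrays numbered 2 and 85.9% without scramble array 1. MAS5 signals near the floor have no firm ratio, and whether dim probe sets account for differences between settings was not tested. The cause of the changes below was not tested, except that fewer genes or arrays enter some settings.

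With no filter 126 genes were called (101 higher, 25 lower) and with the mean of a gene's probe sets 111 (88 and 23). Testing all probe sets gave 113 lower genes. Without the variance trend 7 were called (7 and 0, with 737 lower genes at an unadjusted p under 0.05), with array weights 791 (495 and 296) and without both arrays numbered 2 1224 (694 and 530), which held 228 of the 229. At least 2-fold changes numbered 22 with the mean of a gene's probe sets, 62 with all probe sets, 7 without the trend and 107 with array weights, against 41. Leaving out 1 array gave 66 to 964 genes, 52 to 557 higher and 11 to 407 lower.

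The log2 fold change of MYO10 was no longer past the threshold with no filter (-0.88, limma adjusted p = 0.0821), with the mean of its probe sets (-0.55, 0.149), without _s_at and _x_at probe sets (-0.58, 0.141), without the trend (-0.88, 0.243) and with robust eBayes (-0.88, 0.0565). Leaving out 1 array gave -1.12 to -0.75. The 7 lists became 1 without _s_at and _x_at probe sets, 0 with an estimated correlation and 0 with fry (3 and 5 at an unadjusted p under 0.05), 6 without the trend in camera, and 6 to 9 with 1 array left out. Without _s_at and _x_at probe sets, the ribosomal protein list turned: its median went from 0.087 to 0.053, and camera placed it below the other genes (adjusted p = 0.99, in a range of 1.33e-11 to 0.99).

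The groups share replicate numbers. Deviations of same-numbered samples correlated at 0.0587, 0.163 and 0.0397, not all over 0.1, so the numbers were not taken to pair the samples. Arrays 1 and 3 of both groups correlated best within their own group. The arrays numbered 2 correlated best with each other, across the groups. With the number as a replicate block, 611 genes were called (389 higher, 222 lower), MYO10 stood at -0.88 (limma adjusted p = 0.000789), 69 genes moved at least 2-fold, 7 lists passed, with the cholesterol list lost (camera adjusted p = 0.0521) and the matrix protease list gained (0.032), and 9 of the 19 named genes not called gained a call.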

Other observations

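The tests of scramble array 2 and of the 2 arrays numbered 2 were chosen only after the result was seen, as were the genes of this first paragraph and, once the comparison was known, the patterns weighed below. Several genes outside the fixed lists changed, in both directions (all with limma and Benjamini-Hochberg adjustment). Besides urokinase, the tissue plasminogen activator PLAT fell by 0.62 (adjusted p = 0.0399). The cell cycle kinase CDK6 fell by 0.57 (adjusted p = 0.0102), the microRNA-processing enzyme DICER1 fell by 0.62 (adjusted p = 0.00611) and the immune checkpoint ligand CD274 fell by 0.41 (adjusted p = 0.0469). The interferon-inducible chemokine CXCL11, which no list held, rose by 1.18 (adjusted p = 0.0299). For each of these genes, as for every called gene, the 3 arrays of one group lay to one side of the other 3. The numerically largest fall of a called gene was in SEL1L3, which fell by 2.08 (adjusted p = 0.0474) from a scramble level that varied widely, 8.14 ± 1.21 (SD, n = 3).

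The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05 whatever the data. The real split called 229 genes and the highest other split 0, so 1 of 10 splits reached the real count, although other splits had up to 1322 genes at an unadjusted p under 0.05 against 2108. For gene lists the real split gave 7, and 2 of 10 splits gave as many, with 8 lists in the split that put both arrays numbered 2 with scramble array 1.

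Scramble array 2 lay between the groups: on a scale where 0 is the mean of the other scramble arrays and 1 that of the other knockdown arrays, its median position was 0.488 over the 500 genes with the smallest p without the arrays numbered 2, while each other array held out the same way lay between -0.0468 and 0.0327 or between 0.907 and 0.965. Admixture of knockdown cells or RNA would place MYO10 on this array between the groups, and it lay on the far side of the other scramble arrays (median position -0.329 over the 4 probe sets that were lower), but MYOSIN10 shRNA array 2 was displaced in the same direction (0.308 to 0.872), which may mask a mixture, so admixture and a shared condition cannot be told apart. An exchange of the arrays numbered 2 is argued against by MYOSIN10 shRNA array 2, which sat at 0.871 among the 1224 genes called without both, and RNA degradation by the 3' minus 5' signals of GAPDH and ACTB, of which all 4 on these arrays lay inside the range of the other arrays. What else stays open is a condition shared by the 2 arrays numbered 2, which may have moved them together: their deviations from the group means correlated at 0.163 across genes, the highest of the 9 pairs across groups. These arrays differed from the other 4 in 344 genes, 93 of them higher, and no biological explanation was tested, as the labels name none.

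The upward shift of the interferon list is not carried by the arrays numbered 2, since the list passed without both (limma's camera, adjusted p = 2.59e-06, against a range of 2.53e-10 to 0.266 over its alternatives). Noise of dim probe sets as the sole cause is argued against by the 19 brighter members, of which 16 were positive with a median of 0.18, against 0.44 for the 21 dimmer ones. For the brighter members limma's camera, a model-based test on 3 arrays per group and not an exact one, gave an unadjusted value of 1.37e-05. Both this test and the one without the arrays numbered 2 were run only with the preset correlation of 0.01. With its estimated correlation of 0.039 the whole list on all arrays did not pass (camera adjusted p = 0.266). In 4 of the 9 other splits this list passed too (smallest camera adjusted p = 0.000112). All 9 hold an equal part of the real group difference, so that part does not account for why only some of them passed. An effect of the hairpin or its delivery and an effect of the lower MYO10 cannot be told apart, because the labels name 1 group with a MYO10 hairpin and no rescue, so both stay open as hypotheses.

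The downward shift of the unfolded protein and amino acid stress list was weighed in the same way. It passed without both arrays numbered 2 (camera adjusted p = 0.00211, against a range of 0.000305 to 0.691 over its alternatives, with the call lost at an estimated correlation and, at 0.0533, without scramble array 3), which argues against the arrays numbered 2 as its cause, and it passed in 2 of the 9 other splits (smallest adjusted p = 0.00423). A hypothesis is that the ATF4 branch for amino acid synthesis was lowered and the endoplasmic reticulum chaperones were not lowered alike. The 21 genes of the ATF4 and amino acid part had a mean log2 fold change of -0.28 (17 negative) and the 17 chaperone and degradation genes -0.043 (10 negative), a difference of -0.23 (two-sided permutation p = 0.0207, 100000 permutations over genes, which are not independent replicates). The difference has the direction that the hypothesis predicts. However, the 21 genes include the called ASNS, PSAT1 and ATF4, whose falls were known when this pattern was chosen. The difference is therefore not independent support for the hypothesis, and a test without these genes was not run. Whether culture density or medium differed between the groups, which may act on the same genes, was not tested.

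A hypothesis of copy number or clonal differences between the 2 lines was tested through adjacent genes. Their log2 fold changes correlated at r = 0.0572 over 14127 adjacent pairs, above all 1000 shuffles within chromosomes (highest 0.0427, one-sided permutation p = 0.001, the smallest they can give). Other splits of the arrays gave correlations up to 0.0724, and no run of 15 neighbouring genes stood out (largest mean 0.412, permutation p = 0.106), so such differences and ordinary co-regulation of neighbours cannot be told apart here.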
